A study of Homo sapiens with 8 samples.

How the data were processed

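RNA was measured by sequencing in MiaPaCa-2, an established human pancreatic cancer cell line, 48 h after transfection with either a scrambled control siRNA or an siRNA against BARD1. The labels gave 4 libraries per group, numbered 1 to 4 in each, made from total RNA by purification of polyadenylated transcripts. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They describe a directional and a non-directional protocol as alternatives without saying which was used, and whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

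The deposited table held whole-number read counts per gene for each library. Per the submitters' processing notes, fastp, HISAT2 (version 2.0.5) and featureCounts were used on the human build GRCh37, also named hg19, and the annotation release is not given in the sources used here. The table also held FPKM values by the authors, which equalled the count divided by the gene length and the column total to a relative difference of 5e-12. The authors' deposited table gave log2 fold changes and p-values of their own comparison by a tool not given in the sources used here. 8 further per-sample columns were not used here. The table listed 25945 genes, each with at least 1 read in some library, and a further 22217 rows that named no gene and held 0 reads. Names of 26 genes had been turned into dates and were restored from their identifiers. Of the identifiers, 24678 were found in the name table, and 43 symbols belonged to more than 1 identifier.

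Counts were tested with edgeR (version 4.0.16, R 4.3.3). Genes were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F-test compared 4 BARD1 siRNA with 4 control siRNA libraries without further terms, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled and given as mean ± SD, and each log2 fold change has the standard error (SE) implied by its F statistic. Of the genes in the table, 14528 were tested, 12306 of them protein-coding. Total counts ran from 24458665 to 36212716 per library, so 3 counts, the floor taken here, were worth 0.0828 to 0.123 CPM. Floors cover counting error only. Within groups, no library pair agreed within sampling noise: the chi-square per degree of freedom was 6.06 or more in each pair, over genes with at least 20 reads in the pair.

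38 gene lists were written before the data were examined, and 34 with at least 5 tested members were tested with camera (limma version 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the lists. The camera test with an estimated correlation and fry were run beside it. Named genes were chosen by a rule also fixed before the data were examined. They were BARD1, its partners BRCA1, BRCA2 and PALB2, and the 8 largest rises and 8 largest falls. Those rises and falls were taken among protein-coding genes past the threshold with a mean of at least 5 CPM, a gene name not of clone or LOC form, and no overlap of the groups' ranges. For each list the rule allowed up to 4 members with the smallest p, and the first 2 of each list called are named here. The values of 1 more gene under the rule, which counts of named genes include, are not reported here. All 38 named genes past the threshold moved the same way in all 4 pairs of libraries with 1 number. As the groups' ranges overlapped in none of the 38, by rule in the largest rises and falls, this adds no support of its own. In the test of BARD1 alone, all 70 arrangements of the 8 libraries were enumerated.

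Libraries sharing a replicate number deviated together from their group means. Over 10146 genes the correlations of these deviations were 0.49, 0.487, 0.596 and 0.856 for numbers 1 to 4, so the numbers were taken to pair the libraries. Unlike numbers among 1 to 3 gave 0.366 to 0.51 in the same calculation, so 0.49 and 0.487 show no pairing by themselves. Number 4 with unlike numbers gave -0.699 to -0.551. The pairing comes from the labels' numbers and this check alone. It rests mostly on number 4: within numbers 1 to 3 the correlations were 0.132, 0.074 and 0.233, against -0.186 to 0.08 between unlike numbers. A fit with the replicate number as a block was planned before the data were examined, and its values stand beside the results they change. The biological coefficient of variation was 23.7% without the block and 10.6% with it.

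On counts simulated for this comparison over 14528 genes, with the replicate effects of these libraries and 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, the test without the block recovered 8.96% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 74.2% of those changed 4-fold. No unchanged gene was called. With the block these shares were 70.1%, 83.6% and 95.5%, and 8.29% of the calls were false. The counts were drawn from the block fit itself, with equal changes in all pairs. The shares therefore do not cover effects that differ between pairs, as in the pair numbered 4. A simulated list of 40 genes lowered 1.3-fold was called by camera with the preset correlation (adjusted p = 1.07e-22) and none of the unshifted lists was. With an estimated correlation that list was called without the block (adjusted p = 0.000996) and missed with it (adjusted p = 0.161). Members of all simulated lists were drawn at random, so the outcome gives no error rate for lists whose members vary together.

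Alternatives planned before the data were examined were RLE and upper-quartile scaling, no filter on low counts, a mean of at least 5 CPM, DESeq2 (version 1.42.0), limma-voom, limma on log2(FPKM + 1), protein-coding genes only, the replicate block and leaving out each library. For 3′ UTR sequences, GENCODE release 29 on GRCh38 was matched by gene identifier only, and its coordinates were not mixed with those of the deposited table. In 11803 tested genes with a 3′ UTR of at least 50 bases, the presence of each of 16168 heptamers found in at least 50 genes was related to log2 fold changes limited to ±1.5. UTR length and GC content were covariates, and the lowest and highest t over all heptamers in 1000 permutations of genes set the 5% levels. In simulated data over 11803 genes, all 20 planted heptamers with a log2 shift of -0.15 passed that level, as did 10 of 200 shuffled sets with none planted. The last share follows from the level, which was set on shuffles of the same values, and is no check of errors in the real data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for this step and the figures.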

Results

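The study asked what silencing BARD1 does to the transcriptome of a pancreatic ductal adenocarcinoma cell line. BARD1 encodes the partner of BRCA1 in a ubiquitin ligase that acts in DNA repair by homologous recombination. MiaPaCa-2 cells were transfected for 48 h with control siRNA in 4 libraries or with BARD1 siRNA in 4 libraries, and polyadenylated RNA was sequenced. Total gene counts of the control siRNA libraries 1 to 4 were 24674341, 24458665, 32627983 and 29743948, and those of the BARD1 siRNA libraries 1 to 4 were 36212716, 31701178, 29483415 and 27565777.

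BARD1 (ENSG00000138376, GRCh37 chromosome 2, 215590370 to 215674428) fell in the cells given BARD1 siRNA. Its level was 25.6 ± 3.26 CPM (SD, n = 4) with control siRNA and 3.96 ± 2.49 CPM (SD, n = 4) with BARD1 siRNA, 6.47-fold lower. The log2 fold change was -2.69 (SE 0.36, edgeR adjusted p = 0.00397). The exact permutation test of the 8 values gave p = 0.0286, two-sided, the smallest that 4 against 4 libraries allow, and within the pairs of equal number it gave p = 0.125, the smallest that 4 pairs allow. By replicate number, the share of the control level left was 13.3%, 8.02%, 9.13% and 36.5%, the last in the pair numbered 4. The drop in that pair was smaller by 1.84 on the log2 scale than in the others. The authors' deposited table lists a log2 fold change of -1.81 for BARD1.

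The libraries numbered 4 in both groups stood apart from the rest. The first principal component held 40% of the variance and separated them from the other 6 libraries, while the second, with 22.1%, separated the siRNAs. Between the libraries numbered 4 and the others, 6712 genes differed (edgeR with a term for siRNA), 3206 higher and 3506 lower. Mitochondrial genes took 3.26% and 4.44% of counts in the control and BARD1 siRNA libraries numbered 4, against 0.7% to 2.02% elsewhere. The effect of BARD1 siRNA was smaller in the pair numbered 4 in 607 of the 733 genes changed over all libraries. That pair holds a single library of each siRNA, so differences of its effect from the others are given as sizes only.

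**Figure D1:**
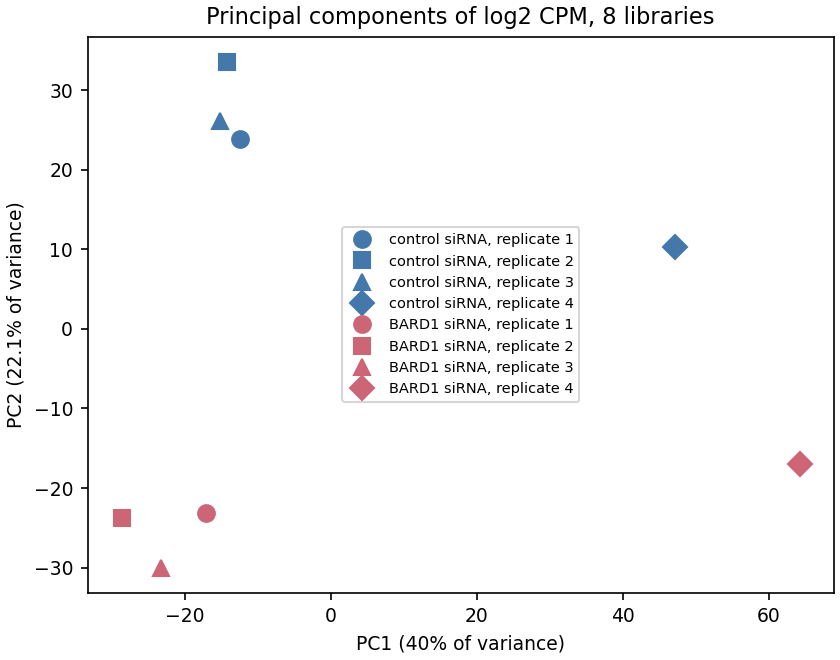
Principal components of log2 CPM over the tested genes, with one point per library, colour for the siRNA and shape for the replicate number; the axes give component scores and their share of variance. The libraries numbered 4 of both groups lie at 47.12 and 64.27 on the first component, and the other libraries lie between -28.72 and -12.52.

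More genes were lower than higher with BARD1 siRNA. Among 7696 genes whose 3′ UTR held neither the octamer ATACAGAA nor its heptamers nor the hexamer TACAGA, 147 were lower and 149 higher. Among the falls, CANX (ENSG00000127022), which encodes the endoplasmic reticulum chaperone calnexin, dropped from 1519 ± 178 to 315 ± 83.0 CPM (SD, n = 4 each), and CCNA2 (ENSG00000145386), a cyclin gene and driver of S phase and mitosis, from 159 ± 35.5 to 48.8 ± 9.09 CPM. HMOX1 (ENSG00000100292), encoding the haem-degrading enzyme haem oxygenase, rose most among the named genes, from 32.9 ± 2.53 to 166 ± 67.2 CPM. Of 14528 genes tested, 733 changed (edgeR, adjusted p under 0.05), 265 higher and 468 lower. Of these, 114 changed at least 2-fold, 49 higher and 65 lower. With the replicate block 3430 genes changed, 1595 higher and 1835 lower, and all 733 were among them with the same sign. Without both libraries numbered 4, an alternative chosen after seeing the data, 4428 genes changed and again included all 733 with the same sign. Without the genes that hold a heptamer of that octamer, also chosen after seeing the data, 195 genes changed, 76 higher and 119 lower. With upper-quartile scaling 413 genes were higher and 470 lower, so the share of higher genes among those changed was 46.8% against 36.2%. The count fell to 194, 200 and 178 without control siRNA library 1, 2 or 3, to 200, 246 and 207 without BARD1 siRNA library 1, 2 or 3, and rose to 2506 without BARD1 siRNA library 4. Without each library numbered 1 to 3, 36 to 52 genes were higher, 142 to 194 lower and 57 to 64 changed at least 2-fold, and without BARD1 siRNA library 4 these counts were 1243, 1263 and 304. The authors' deposited table lists 1241 genes with an adjusted p under 0.05, 548 higher and 693 lower, and 725 of the 733 were among them with the same sign.

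The largest falls after BARD1 are ranked among genes that met the naming rule, with a mean of at least 5 CPM. First were CANX (log2 fold change -2.27, SE 0.18, edgeR adjusted p = 0.00031) and ID2, which encodes an inhibitor of helix-loop-helix transcription factors (-1.82, SE 0.32, adjusted p = 0.014). They were followed by CCDC86 at -1.77, the ubiquitin ligase gene RNF26 at -1.76, CCNA2 at -1.71, the vesicular transporter gene SLC18B1 at -1.63, the ESCRT component gene VPS37A at -1.62 and the kinase gene MAP4K5 at -1.60. Adjusted p in these 6 genes ran from 0.000322 in MAP4K5 to 0.0418 in SLC18B1. CANX lies on GRCh37 chromosome 5 at 179105629 to 179157926 and CCNA2 on chromosome 4 at 122737599 to 122745087. RNF26 and MAP4K5 fell by 0.92 and 1.03 on the log2 scale in the pair numbered 4, drops smaller by 1.16 and 0.77 than in the others. The 3′ UTRs of CANX, RNF26, CCNA2, SLC18B1, VPS37A and MAP4K5 hold the octamer ATACAGAA, and that of CCDC86 holds a heptamer of it. CANX fell by 1.52 on the log2 scale in the pair numbered 4, a drop smaller by 1.03 than in the others. Without one library, SLC18B1 missed the threshold in 7 of 8 cases, all but without BARD1 siRNA library 4 (adjusted p up to 0.135). ID2 missed it without control siRNA library 3 or BARD1 siRNA library 1, 2 or 3 (adjusted p up to 0.0621).

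The largest rises, ranked under the same rule, were in HMOX1 (log2 fold change 2.34, SE 0.27, edgeR adjusted p = 0.00168) and the zinc finger gene ZNF469 (2.11, SE 0.30, adjusted p = 0.00576). They were followed by TRIB1, a pseudokinase gene, at 1.54, PRTG at 1.53, the acetylcholinesterase gene ACHE at 1.49, the integrin gene ITGA10 at 1.33, IRAK2, a kinase gene of Toll-like receptor signalling, at 1.33, and the syntaxin gene STX3 at 1.31. Adjusted p in these 6 genes ran from 0.00531 in ACHE to 0.0215 in IRAK2 and STX3. HMOX1 lies on GRCh37 chromosome 22 at 35776354 to 35790207. HMOX1 rose by a log2 difference of 1.49 in the pair numbered 4 and 2.23 to 2.81 in the others, and STX3 by 0.25 and 1.09 to 1.88. HMOX1, ZNF469 and ACHE passed the threshold without each library in turn. TRIB1, PRTG, IRAK2 and STX3 missed it without each library numbered 1 to 3, and ITGA10 without each of these but BARD1 siRNA library 2 (adjusted p up to 0.0911 in STX3).

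**Figure D2:**
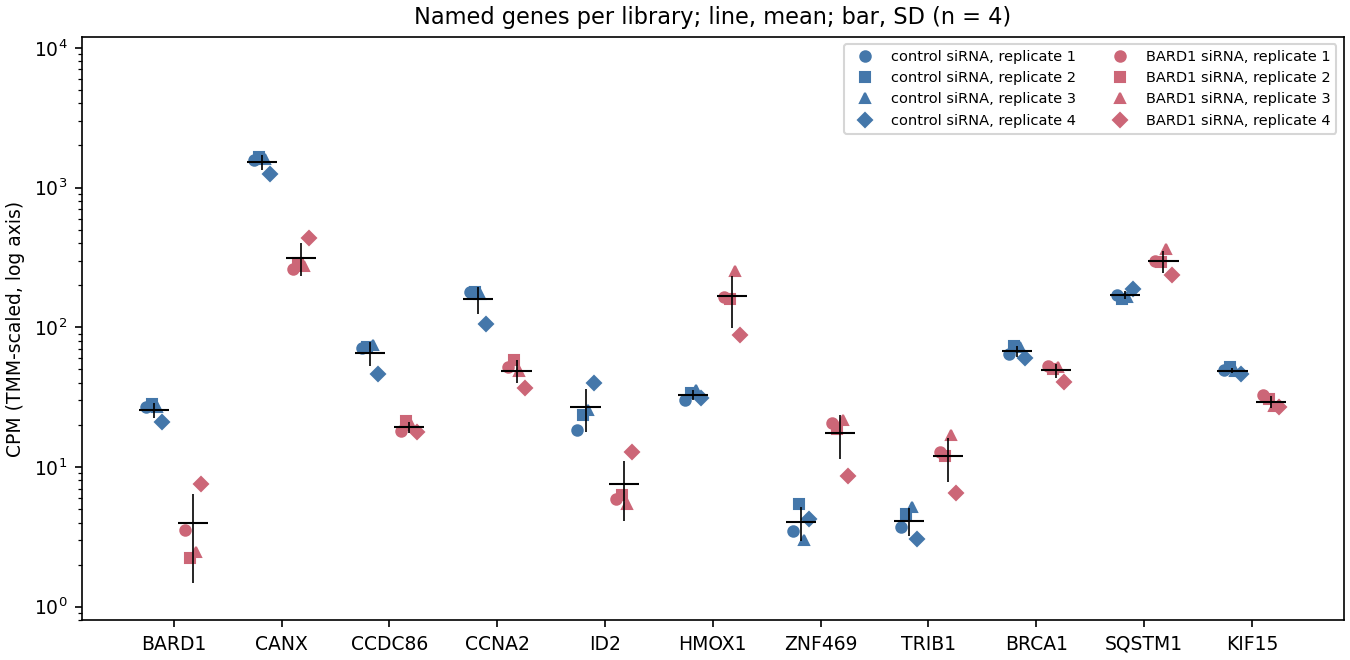
CPM per library on a log axis for 11 named genes, with colour for the siRNA, shape for the replicate number, lines for the mean and bars for the SD of 4 libraries. BARD1 falls from a mean of 25.6 to 3.96 CPM, CANX falls from 1519 to 315 CPM and HMOX1 rises from 32.9 to 166 CPM.

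The partners of BARD1 in homologous recombination moved less. BRCA1 fell from 67.5 ± 6.14 to 49.1 ± 5.59 CPM (SD, n = 4 each, log2 fold change -0.46, SE 0.11, edgeR adjusted p = 0.0386). The BRCA1 3′ UTR also holds ATACAGAA. BRCA2 did not pass the test (-0.24, SE 0.24, adjusted p = 0.681), with log2 fold changes from -0.41 without BARD1 siRNA library 2 to -0.04 without BARD1 siRNA library 4. PALB2 did not pass either (-0.08, SE 0.12, adjusted p = 0.81). Of 41 homologous recombination genes, 6 fell, 0 rose and 35 did not pass, and 10 fell when adjusted over the list alone. RMI2, of the complex that dissolves joined DNA strands, was at -0.59 (SE 0.11, adjusted p = 0.0199). The list's median was -0.15 (camera adjusted p = 0.000474), and the adjusted p was 0.433 with an estimated correlation. The median was -0.09 in members without the octamer or its heptamers in the 3′ UTR, and -0.19 in the libraries numbered 4 against the rest. With the replicate block 15 of these genes fell and 1 rose. BRCA1 and RMI2 each missed the threshold without each library numbered 1 to 3 (adjusted p up to 0.142 in BRCA1).

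Other DNA repair lists were also lower, but the lists share members, so their calls are not independent. UBE2T was in the Fanconi anaemia and BRCA1 complex lists, and RFC4 in the checkpoint and DNA replication lists. Of 18 Fanconi anaemia genes 5 fell, 9 when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.000161, and adjusted p = 0.135 with an estimated correlation). FANCI was at -0.48 (SE 0.10, edgeR adjusted p = 0.0219) and FANCA at -0.37 (SE 0.07, adjusted p = 0.0219), and with the block 9 members fell. Of 24 DNA damage checkpoint genes 5 fell, and adjusted over the list alone 7 fell and 1 rose (median -0.20, camera adjusted p = 0.000312, and adjusted p = 0.354 with an estimated correlation). They included RFC4, of the clamp loader, at -0.64 (SE 0.09, adjusted p = 0.00473), and TIMELESS, of the replication fork protection complex, at -0.41 (SE 0.08, adjusted p = 0.0175). With the block 13 checkpoint genes fell and 2 rose. The 3′ UTRs of FANCI and TIMELESS hold a heptamer of ATACAGAA, while those of FANCA and RFC4 hold none. Without one library FANCI and FANCA missed the threshold in each of the 6 cases numbered 1 to 3, and TIMELESS in those but BARD1 siRNA library 3 (adjusted p up to 0.0951), while RFC4 passed each time. The checkpoint median was -0.13 without BARD1 siRNA library 4, and -0.24 in the libraries numbered 4 against the rest.

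Of 25 genes of BRCA1 complexes and H2A ubiquitin signalling 3 fell, and adjusted over the list alone 6 fell and 2 rose (median -0.12, camera adjusted p = 0.0121, and adjusted p = 0.515 with an estimated correlation). FAM35A, of the shieldin complex that limits end resection, fell from 72.7 to 28.7 CPM (log2 fold change -1.34, SE 0.17, edgeR adjusted p = 0.00274), and its pseudogene copies make its count uncertain. UBE2T, a ubiquitin-conjugating enzyme gene, was at -0.61 (SE 0.14, adjusted p = 0.0354). With the block 9 of these genes fell and 2 rose, and the median in the libraries numbered 4 against the rest was -0.23. Of 23 base excision repair and PARP genes 3 fell, 4 when adjusted over the list alone (median -0.09, camera adjusted p = 0.0316, and adjusted p = 0.256 with an estimated correlation). PARP1 fell from 531 to 376 CPM (-0.50, SE 0.08, adjusted p = 0.00854) and APTX was at -0.54 (SE 0.11, adjusted p = 0.0231), and with the block 6 members fell. The PARP1 3′ UTR holds a heptamer of ATACAGAA, while those of APTX, UBE2T and FAM35A hold none. The BRCA1 complex list was not called without BARD1 siRNA library 4 (adjusted p = 0.219), nor the base excision list without control siRNA library 4 (adjusted p = 0.0622) or BARD1 siRNA library 2 (adjusted p = 0.0576). The base excision median was -0.24 without BARD1 siRNA library 4. UBE2T and APTX missed the threshold without each library numbered 1 to 3 (adjusted p up to 0.128), and PARP1 without control siRNA library 3 (adjusted p = 0.0523).

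In the list of G2/M and mitosis, 6 of 47 genes fell and 0 rose, 22 fell when adjusted over the list alone, and 46 fell with the replicate block. The list's median log2 fold change was -0.45 (camera adjusted p = 2.76e-19, and adjusted p = 0.38 with an estimated correlation). The smallest p were those of CCNA2 (-1.71, SE 0.19, edgeR adjusted p = 0.00168) and the mitotic kinesin gene KIF15 (-0.74, SE 0.09, adjusted p = 0.0029). Of 46 genes of DNA replication and E2F targets 6 fell and 0 rose, and adjusted over the list alone 18 fell and 1 rose (median -0.27, camera adjusted p = 3.93e-10, and adjusted p = 0.38 with an estimated correlation). CHAF1B, of a histone chaperone, was at -0.55 (SE 0.08, adjusted p = 0.0047). With the block 31 of these fell and 1 rose. The libraries numbered 4 of both groups were also lower than the rest in both lists, with medians of -0.59 in G2/M and mitosis and -0.28 in DNA replication. Without BARD1 siRNA library 4 the BARD1 siRNA medians were -0.30 in G2/M and mitosis and -0.18 in DNA replication, and both lists were still called.

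The lists that rose held stress, signalling and lysosomal genes. Of 21 NRF2 targets, genes of the antioxidant response, 2 rose and 1 fell, and 8 rose when adjusted over the list alone (median 0.34, camera adjusted p = 5.89e-05, and adjusted p = 0.256 with an estimated correlation). HMOX1 was the gene with the smallest p, and the gene that fell was the drug export gene ABCC2 (-0.67, SE 0.12, edgeR adjusted p = 0.0153), whose 3′ UTR holds ATACAGAA. Of 30 autophagy and lysosome genes 6 rose, 12 when adjusted over the list alone (median 0.25, camera adjusted p = 4.24e-05, and adjusted p = 0.256 with an estimated correlation). The autophagy receptor gene SQSTM1 rose from 171 to 299 CPM (0.81, SE 0.13, adjusted p = 0.00854) and LAMP2 was at 0.37 (SE 0.08, adjusted p = 0.0282). The rise of SQSTM1 was 0.33 in the pair numbered 4 and 0.81 to 1.15 in the others. With the block 12 NRF2 targets and 13 autophagy and lysosome genes rose, and 1 and 2 fell. ABCC2 missed the threshold without control siRNA library 1, 2 or 3 or BARD1 siRNA library 1 or 2, and LAMP2 without each library numbered 1 to 3 (adjusted p up to 0.119).

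Of 22 ERK pathway output genes 4 rose, 7 when adjusted over the list alone (median 0.28, camera adjusted p = 5.95e-05, and adjusted p = 0.256 with an estimated correlation). The feedback inhibitor gene SPRY4 rose from 284 to 421 CPM (log2 fold change 0.57, SE 0.10, edgeR adjusted p = 0.0135), and IER3 was at 0.73 (SE 0.15, adjusted p = 0.0272). Of 16 immediate early genes 2 rose, IER3 and JUN (0.41, SE 0.08, adjusted p = 0.0252), with a median of 0.24 (camera adjusted p = 0.0125, and adjusted p = 0.313 with an estimated correlation), and 2 rose when adjusted over the list alone. In the pair numbered 4 the log2 difference was 0.09 in IER3 and 0.14 in JUN, against 0.78 to 1.16 and 0.44 to 0.55 in the others. The immediate early list had a median of 0.47 in the libraries numbered 4 against the rest, and its BARD1 siRNA median was 0.59 without control siRNA library 4 and 0.10 without BARD1 siRNA library 4. Of 30 genes of the integrated stress and unfolded protein responses 2 rose, 4 when adjusted over the list alone (median 0.15, camera adjusted p = 0.00131, and adjusted p = 0.513 with an estimated correlation). They were SESN2 (0.60, SE 0.13, adjusted p = 0.0314) and HERPUD1 (0.49, SE 0.12, adjusted p = 0.0487). With the block 11 ERK output genes, 6 immediate early genes and 9 stress response genes rose, and 1 of the last fell. The stress response list was not called without control siRNA library 4 (adjusted p = 0.0586), and its median was 0.23 without BARD1 siRNA library 4. IER3, JUN, SESN2 and HERPUD1 missed the threshold without each library numbered 1 to 3, SPRY4 without each of these but BARD1 siRNA library 2, and HERPUD1 also without control siRNA library 4 (adjusted p up to 0.157 in HERPUD1).

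**Figure D3:**
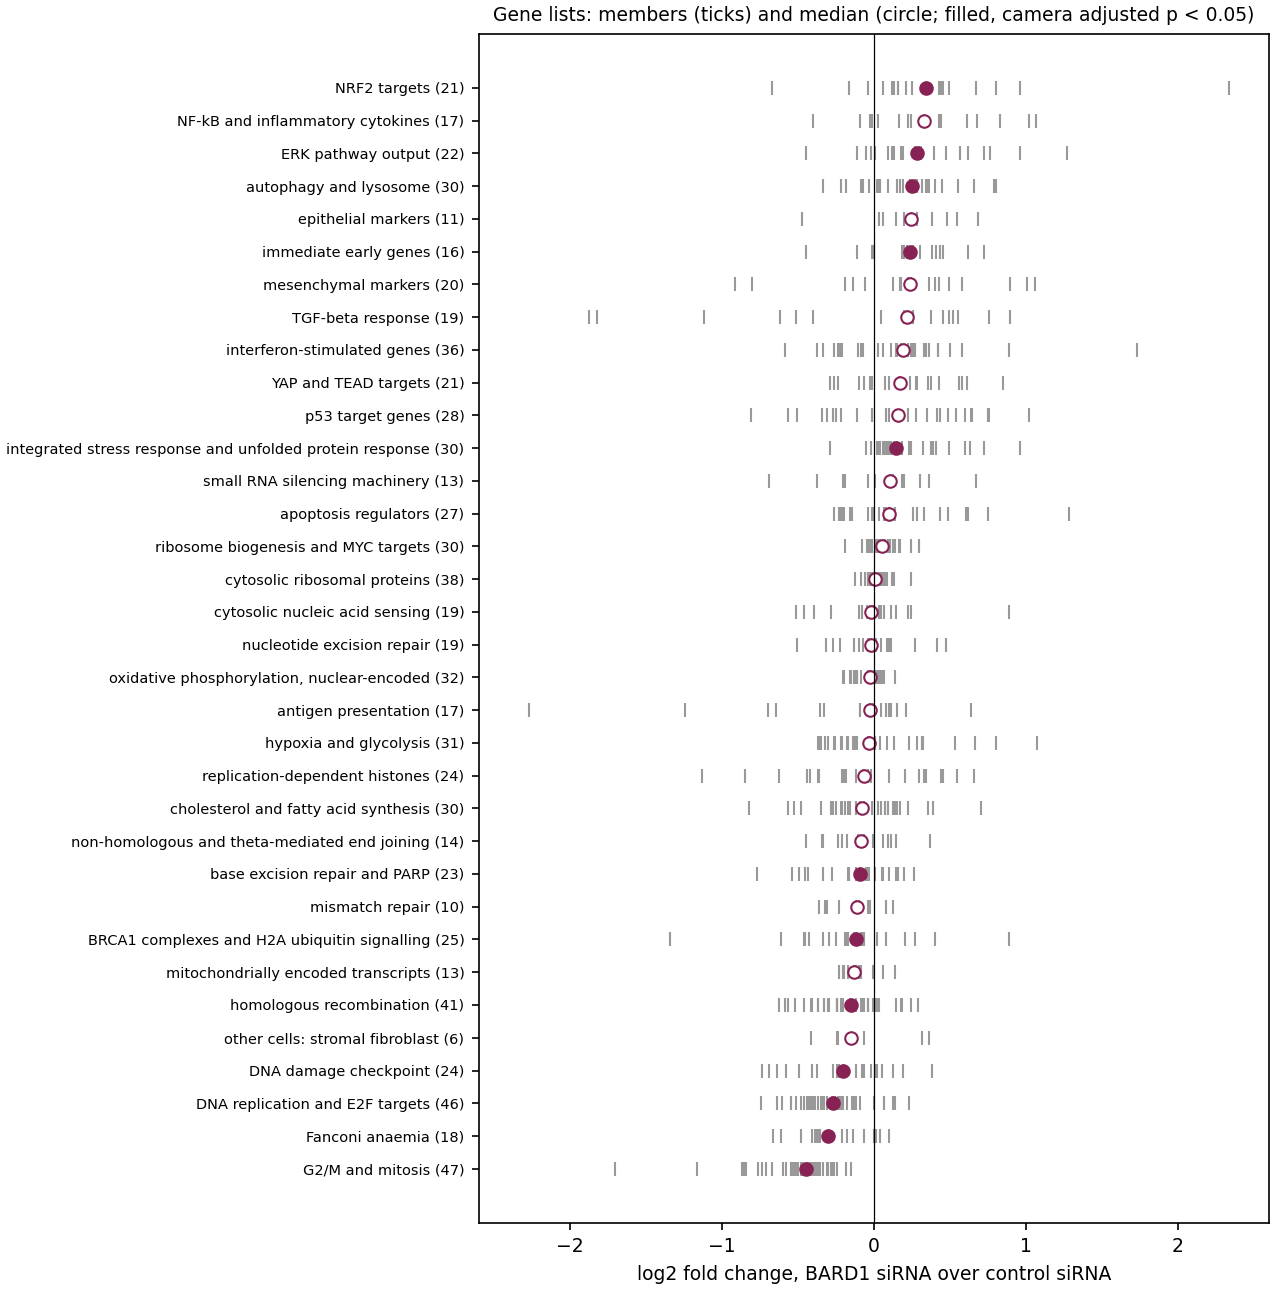
Log2 fold changes (BARD1 siRNA over control siRNA) of the tested members of 34 gene lists, as ticks, with the list median as a circle that is filled where camera with the preset correlation gave an adjusted p under 0.05; the number of members tested follows each name. Medians run from -0.45 in G2/M and mitosis to 0.34 in NRF2 targets, and 12 lists are filled, 7 lower and 5 higher.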

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

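The test of COL1A1, DCN and LUM in this part and the count of shared genes in the test of GC content were chosen after the results were seen, the first in place of an earlier fibroblast test whose result is also given.

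In 84 groups of 4 values, over 40 named genes, total counts and mitochondrial shares, 6 held a library far from the other 3 by Dixon's criterion, where chance gives about 1 in 20, or 4.2. All 6 were libraries numbered 4. Among control siRNA libraries, number 4 was lowest for BARD1, at 20.8 CPM against 26.9 to 28.0, for CCDC86, at 46.1 against 70.6 to 74.0, and for CCNA2, at 106 against 174 to 180. Among BARD1 siRNA libraries, number 4 was lowest for PRTG, at 13.6 CPM against 33.8 to 35.6, and highest for CANX, at 439 against 261 to 286, and for ID2, at 12.7 against 5.43 to 6.27.

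The pattern weighed was that the libraries numbered 4 stood apart, with 6712 genes differing from the rest. Lower depth was argued against, since the totals of these libraries, 29743948 and 27565777, lay within the range of the others, 24458665 to 36212716 (6640 genes differed after thinning to the lowest total), and GC content and gene length were argued against as the whole cause, since 5017 of 6299 genes differed in the same direction once smooth trends of both were removed from each library, with 6288 differing in all and a median absolute log2 difference of 0.44 against 0.47 before. A first fibroblast test, set before its result, came out on the side of fibroblast RNA: 12 fibroblast genes summed to 1160 and 1190 CPM in the libraries numbered 4 of control and BARD1 siRNA, against 463 to 758 in the others, but nearly all of this was COL1A2, at 434 to 718 CPM in the others too. C7 was also higher in the libraries numbered 4, at 5.35 and 7.6 CPM against 0.585 to 1.16. So were COL3A1, at 32.9 and 26.8 against 12.6 to 20.2, and FBLN1, at 26.5 and 26.8 against 11.8 to 18.2. The test that replaced the first, on 3 of those 12 genes, argued against fibroblast RNA as the source of the genes lower there. COL1A1, DCN and LUM, abundant in fibroblasts, together reached at most 2.04 CPM in these libraries. Genes lower there had a median drop of 24.4% after TMM scaling. That is only a rough guide to the share foreign RNA would need to fill. A difference in culture, transfection or library batch stays open and untested, since the labels name none, and no biological explanation was tested.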

How the results depend on the processing

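Leaving out both libraries numbered 4, a term for them, leaving out genes that hold the heptamers ATACAGA or TACAGAA in their 3′ UTR, and fry and the estimated correlation within the block were chosen after seeing the data. BARD1 stayed lower and past the threshold under every alternative run, with log2 fold changes from -3.29 to -1.74. The counts of genes changed, genes higher, genes lower and genes changed at least 2-fold were 733, 265, 468 and 114. The replicate block gave 3430, 1595, 1835 and 214, a term for the libraries numbered 4 gave 3730, 1765, 1965 and 236, and leaving out both gave 4428, 2185, 2243 and 339, with all 733 genes called in each. DESeq2 gave 1264 changed, 560 higher and 704 lower. Upper-quartile scaling gave 413 higher, a mean of at least 5 CPM gave 467 higher over 10142 genes, and limma on log2(FPKM + 1), a scale that shrinks low genes, gave 47 changed at least 2-fold. Leaving out the genes that hold the heptamers, so that fewer genes were tested, gave 195 changed, 76 higher, 119 lower and 39 at least 2-fold. Leaving out one library gave 178 to 2506 changed, 36 to 1243 higher, 142 to 1263 lower and 57 to 304 at least 2-fold, with fewer samples in each fit. Apart from these constructions, the cause was not tested.

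Of 34 lists tested, 12 gene lists changed, 19 without both libraries numbered 4, and 10 to 18 without one library. With an estimated correlation camera called 0 of them without the block and 0 with it, where 6 and 4 lists had an unadjusted p under 0.05, and fry called 9 and 14, with 6 and 11 of the 12 lists among them. The block added calls for 6 lists and removed none, and it changed no other call among the lists or named genes. PALB2, not called in any fit, changed sign without control siRNA library 3, to 0.03, and ranged from -0.13 to 0.03 without one library (PALB2 log2 fold change). The other named genes and called lists kept their sign under every alternative run, and of the 38 named genes called 23 missed the threshold without at least 1 library. Apart from leaving out libraries, SLC18B1 missed it with upper-quartile scaling, HERPUD1 and LAMP2 with no filter, STX3 and HERPUD1 with limma-voom, and 6 genes without those that hold the heptamers. In the simulation at these depths 8.96% of genes changed 1.5-fold were recovered without the block, and 70.1% with it, where 8.29% of calls were false. Simulated changes were equal in all pairs, unlike those in the pair numbered 4. Depth limits genes near the floor of 3 counts, 0.0828 to 0.123 CPM, and was not varied in the simulation.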

Other observations

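Tests of the control siRNA seed, of seed matches within the G2/M list and of lists with an estimated correlation in the block fit were chosen after the results were seen.

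Several other lists were not called by camera with or without the block. The 38 cytosolic ribosomal protein genes had a median log2 fold change of 0.01 (camera adjusted p = 0.74) and the 32 nuclear genes of oxidative phosphorylation -0.02 (adjusted p = 0.581). Of 28 p53 targets 1 rose and 2 fell, and 5 rose and 3 fell when adjusted over the list alone (median 0.16, camera adjusted p = 0.346), and with the block 11 rose and 5 fell. Of 36 interferon-stimulated genes 1 rose and 1 fell, also when adjusted over the list alone (median 0.19, camera adjusted p = 0.369). Their median was 0.86 in the libraries numbered 4 against the rest, where antigen presentation genes were at 0.63 and mitochondrially encoded transcripts at 1.43. Non-homologous end joining was at -0.09 (camera adjusted p = 0.369), mismatch repair at -0.11 (adjusted p = 0.185, although fry gave an adjusted p = 0.0323) and nucleotide excision repair at -0.02 (adjusted p = 0.981).

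Another 6 lists passed in camera with the preset correlation when the replicate block was used and not without it. With fry, epithelial markers (adjusted p = 0.00621) and mesenchymal markers (adjusted p = 0.0327) also passed without the block. Mesenchymal markers had a median of 0.24 (camera adjusted p = 0.0545, and 0.00358 with the block), epithelial markers 0.25 (adjusted p = 0.124, and 0.00991 with the block), NF-kB and inflammatory cytokine genes 0.33 (adjusted p = 0.0577, and 0.0318 with the block) and apoptosis regulators 0.10 (adjusted p = 0.0561, and 0.0318 with the block). YAP and TEAD targets were at 0.17 (adjusted p = 0.246, and 0.0442 with the block) and mitochondrially encoded transcripts at -0.13 (adjusted p = 0.369), with a median of -0.40 in the block fit (adjusted p = 0.0401). In MT-CO1, chosen after its values were seen, the log2 difference was -0.60, -1.61 and -0.32 in the pairs numbered 1 to 3 and 0.38 in the pair numbered 4. None was called with an estimated correlation in the block fit (lowest adjusted p = 0.343).

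Of the 35 splits of the 8 libraries into groups of 4, 1, the real one, gave as many genes changed as 733, and likewise 1 for the 265 genes higher, 1 for the 468 lower and 1 for the 114 changed at least 2-fold. As the numbers pair the libraries, the real split compares with the 8 splits that part all 4 pairs, of which 1, the real one, gave each of these counts, and 8 are too few for a share under 0.05; the others keep at least 1 pair together. The highest of the other splits was 0 in each case with edgeR, with 45 to 3379 genes at an unadjusted p under 0.05 against 2745 in the real split. For the 12 gene lists called, 15 of 35 splits gave as many and the highest other gave 16, so chance cannot be excluded for that count. Among the 8 splits that part all 4 pairs, 2 gave at least 12 lists, the real one included, and 11 of the 15 splits that keep both libraries numbered 4 together reached it. With the block, where the same 8 splits are too few, 1, the real one, gave 3430 genes and the highest other gave 0.

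The second pattern weighed was the fall of genes with BARD1 siRNA, for which a candidate explanation is pairing of the siRNA's seed with 3′ UTRs of other genes. Of 16168 heptamers, ATACAGA had the lowest t for lower log2 fold changes, -17.82 against a 5% level of -4.55 (permutation p = 0.000999, the smallest the permutations allow), at -15.95, -14.64, -14.33 and -9.99 in the pairs numbered 1 to 4, while no heptamer went below -5.68 in the contrast of the libraries numbered 4; it occurred in 42.8% of the 453 lower genes with a 3′ UTR and 11.3% of other genes. The 639 genes with the octamer ATACAGAA had a median of -0.17, with 122 lower and 3 higher. Of 1961 genes with a heptamer of it but not the octamer, 141 were lower and 52 higher. Of 1507 with only the hexamer TACAGA, 43 were lower and 43 higher. The 7696 genes with none of these had a median of 0.01, with 147 lower and 149 higher. Matches in 3′ UTRs could thus account for part of the lower genes. Of these, 263 of 453 held the octamer or a heptamer of it, against 55 of 247 higher genes. As ATACAGA was picked on these same values, the counts are no separate support. ATACAGA occurs once in the BARD1 transcript ENST00000260947.8, in GCGGCCTGTCGATTATACAGATG within the coding part of exon 7 of 11 (GRCh38 chromosome 2, 214752520 to 214752526), although 25.2% of all heptamers occur in that transcript, and the siRNA sequence is not given in the sources used here. Among higher genes TGACTAA had the highest t, 4.89 against a 5% level of 4.54 (permutation p = 0.011). TTGACTA, which overlaps it, followed at 4.80 (permutation p = 0.015). The t of TGACTAA was 3.52 to 4.5 over the pairs. Genes with the octamer TTGACTAA had a median of 0.085, those with a heptamer of it 0.045 and those with none of these or its hexamer -0.007. In the pair numbered 4 the octamer median was -0.032. These heptamers too were picked on these same values. A t larger in size, -5.68, arose in the contrast of the libraries numbered 4, which holds both siRNAs equally. In that contrast TGACTAA was at 1.49. The values for TGACTAA go with a weak seed effect of the control siRNA. As a larger t arose without a contrast of siRNAs, they cannot tell it from other differences between libraries. An effect of lower BARD1 itself stays open and untested, because the design holds no second BARD1 siRNA.

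The third pattern weighed was the fall of G2/M and mitosis genes. Seed matches in their own 3′ UTRs were argued against as the whole cause: the 41 members with neither heptamer had a median log2 fold change of -0.434 (camera adjusted p = 8.15e-15, and adjusted p = 0.433 with an estimated correlation), and 40 of them fell with the replicate block. Slower cycling after the loss of BARD1, or after the fall of a few cycle genes that hold the octamer, such as CCNA2, may each be a source, and no value here tells these apart.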
